A study of Mus musculus with 3 samples.

How the data were processed

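Gene expression was measured by RNA sequencing in 3 pooled libraries of dorsal root ganglion (DRG) cells sorted by flow cytometry from mouse embryos at 12.5 days post coitum. The embryos carried an EGFP reporter of Ret, the receptor tyrosine kinase for GDNF family ligands. Per the labels, library B pooled 340 ganglia from 17 embryos (10 male, 7 female), library C 300 ganglia from 15 embryos and library D 60 ganglia from 3 embryos, all from segments between the lower thoracic and first sacral levels. The sample labels name a transgene while the series text describes EGFP knocked into one Ret allele, and this conflict was not resolved. Per the labels' protocols, RNA was turned into cDNA with a low-input kit that does not mark strand. The libraries are separate pools and form a single group, with no second condition.

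The authors deposited one table per library with raw read counts, CPM and RPKM for 41388 Ensembl genes with exon coordinates and a gene length. The submitters' processing notes name Subread, featureCounts 1.4.5 and the mouse build GRCm38.p2 without giving their roles. The annotation release, the strand setting and any filter on reads are not given in the sources used here. In the deposited tables, CPM equals the count divided by the file total, and the deposited RPKM equals that CPM divided by the length in kilobases. The deposited counts were used for all results. Symbols were available for 40254 identifiers and 1134 stayed without one.

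TPM was computed from count and gene length over all genes of a file. A gene was taken as detected at 1 TPM or more in every library. Lists were compared with 10000 random lists matched on gene length in 10 bins, using the median of log2(TPM + 0.1), as a description of these libraries. Log2 ratios of genes or list medians were computed within each library and given as mean ± SD. With 3 libraries an exact two-sided sign-flip test cannot give a p below 0.25, so no such ratio can pass 0.05.

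Library D, which came from the fewest embryos, was set against B and C with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg threshold 0.05). This design has 1 residual degree of freedom and assumes that the lone library varies like the others. The same fit was run with B alone and with C alone. Standard errors of log2 ratios are approximate, taken from the ratio and its F statistic. Lists of 4 or more tested members were compared by camera in limma 3.58.1 with a preset correlation of 0.01. With an estimated correlation, an alternative setting, camera has 1 residual degree of freedom and can hardly pass any list. Spread between pools was the edgeR biological coefficient of variation. Tested on simulated counts at the spread of the D comparison, the fit recovered 91% of 200 genes changed 16-fold and 7% of those changed 4-fold, over 15205 and 15224 genes. The simulation gave every gene the same spread, whereas in the real D comparison the spread differed between genes. These shares may therefore be too high for the real fit and do not bound what it missed. Of 100 random lists of the neuron list's size, drawn from 23553 genes, 2 lay above the 95th percentile. These lists came from the same genes as the random lists they were set against. The check therefore covers the calculation only, not the choice of those genes.

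Alternatives included other detection limits and pseudocounts, CPM without length, each library left out, DESeq2 1.42.0, its size factors and no filter. A correction was added after seeing the data: a smooth surface of log length and transcript GC per library, fitted with mgcv 1.9.3 on genes with a mean count of at least 10 and used as an offset. GC came from the longest GENCODE M21 transcript and was known for 99.0% of genes with a count. TPM over protein-coding genes, the tests of library C and the list tests of B and C were also added then.

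The lists (23 of genes and 14 of cell type markers) and the rule for naming genes were fixed before the data were examined. The rule names every member of the RET complex and neurotrophin receptor lists, the 4 members with the highest mean TPM of each other list, members under the detection limit, the 20 genes with the highest mean TPM, each Hox gene, and, where no gene passed in library D, the 5 higher and 5 lower genes with the smallest p as values only. Results for some genes these rules name are not reported here. Of the 466 genes tabulated from the lists and the top genes, 100 share exon bases with another gene. Reads of such genes cannot be assigned with certainty without strand, and reads of near-identical copies such as the adult globins are likewise uncertain.

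Total counts were 18072199 in B, 11666241 in C and 20966139 in D. A count of 0 allows up to 3 counts, which is 0.166, 0.257 and 0.143 CPM in B, C and D. Such limits cover counting error only, because PCR reads without molecular identifiers are not independent molecules.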

Results

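Pools of Ret-EGFP cells from embryonic mouse DRG were profiled, with 340, 300 and 60 ganglia behind libraries B, C and D. Total counts ranged from 11666241 in C to 20966139 in D. At 1 TPM or more, 11896 genes were detected in every library. To look for duplicate libraries, the counts of each pair were set against counting error alone. The chi-square per degree of freedom was 133 for B and C, 264 for B and D and 318 for C and D, so no pair was counted as 1 library; it says nothing of how the pools differ biologically. The biological coefficient of variation across the 3 pools was 0.51 over 13182 genes. P-values below do not measure the spread between these pools alone. The fits with a lone library have 1 residual degree of freedom and borrow spread across genes. Camera at its preset correlation sets the genes of a list against other genes, nearly as if genes were independent.

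Cytoskeletal and neuronal messages were among the most abundant. Tmsb4x, which encodes an actin-sequestering peptide, stood at 22351 ± 5668 TPM (SD, n = 3), and Sncg, the gene of gamma-synuclein, at 16418 ± 6995 TPM. The tubulin genes Tuba1a and Tubb3 followed with 12984 ± 3146 and 12294 ± 4861 TPM. All 14 neuron markers were detected in each library, and so were all 21 genes of the cytoskeleton and axon growth list. The medians of both lists lay above all random lists in every library. Both lists hold Tubb3, Stmn2, Gap43, Dcx, Nefl, Nefm and Prph, so they are not separate evidence. Stmn2 and Gap43, whose products act in axon growth, reached 8106 ± 1697 and 4398 ± 1080 TPM. Mir6236, Gm23935, Gm42418 and Gm15564 also stood among the 20 highest genes. Together with Lars2, these features, grouped after their values were seen, took 0.76% of counts in B, 4.89% in C and 0.74% in D.

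The sort selected cells by the Ret reporter, and the first comparison asks how Ret stands against its co-receptors and the Trk receptors of other DRG classes. Ret (ENSMUSG00000030110, chromosome 6, 118151748 to 118197744, GRCm38) was measured at 40.4 ± 18.0 TPM (SD, n = 3). If EGFP was knocked into a Ret allele and stops its transcription, this value and each ratio to Ret come from the other allele alone; the sources used here leave that open. Gfra3, the artemin co-receptor, stood at 230 ± 98.9 TPM, Gfra2, the neurturin co-receptor, at 150 ± 106 TPM and Ncam1 at 82.3 ± 61.6 TPM. Gfra3 exceeded Ret in 3 of 3 libraries, by a log2 ratio of 2.51 ± 0.29, and Gfra2 exceeded Ret in 3 of 3, by 1.75 ± 0.58. Gfra1, the GDNF co-receptor, stood at 56.6 ± 47.2 TPM. It did not differ from Ret beyond the spread between libraries: the log2 ratio was -0.12 in B, 0.03 in C and 0.87 in D, with a mean of 0.26 ± 0.53. Gfra4 was below 1 TPM in B and D and at 3.62 TPM in C, and Gfral had no counts. Exons of Gfra1, Gfra4 and Ncam1 overlap those of other genes.

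Among neurotrophin receptors, Ngfr, which encodes p75, was highest at 160 ± 63.6 TPM. Ntrk2 and Ntrk3, the genes of TrkB and TrkC, stood at 18.6 ± 6.91 and 9.74 ± 4.81 TPM, and Sort1 at 9.84 ± 7.25 TPM. Ret exceeded Ntrk2 in 3 of 3 libraries, with a log2 ratio of 1.09 ± 0.36 (SD, n = 3), and Ntrk3 in 3 of 3, with 2.11 ± 1.04. Both gave an exact sign-flip p = 0.25, the smallest that 3 libraries allow. The Ret over Ntrk2 ratio was 0.18 with CPM, since the counted Ntrk2 gene is 13806 bases long and Ret 7341. In counts Ret stood below Ntrk2 in B, with 1782 against 2075, and above it in C and D.

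**Figure D1:**
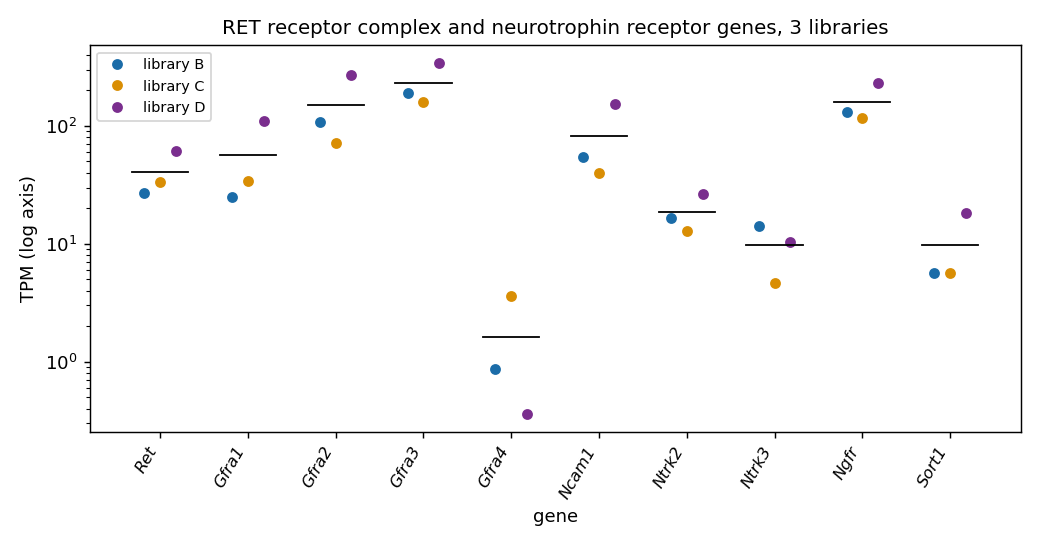
TPM of RET receptor complex and neurotrophin receptor genes on a log axis, with a point per library and a black line at the mean. Gfra3 and Gfra2 lie above Ret in each library, and Ntrk2 and Ntrk3 lie below it.

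Ligand genes were low. Of the 5 GDNF family ligands, none was detected in every library; Gdnf itself stood at 1.47 ± 0.76 TPM, and Nrtn, Artn, Pspn and Gdf15 were under 1 TPM in each library. Of the neurotrophins, Bdnf and Ntf3 were detected, at 4.73 ± 0.61 and 3.55 ± 1.57 TPM; Ntf5 was not. Of 21 RET signalling adaptors and targets, 18 were detected. Dok5, an adaptor, stood at 226 ± 35.6 TPM. Spry2 and Grb10 had higher means, 309 ± 473 and 275 ± 398 TPM, which rest on D with 856 and 735 TPM, against 37.0 and 49.1 in B and 34.8 and 41.2 in C.

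Genes of several DRG classes were found side by side. Of the early Ret mechanoreceptor list 10 of 11 genes were detected, including Maf at 20.4 ± 8.56 TPM; Npy2r was under 1 TPM. Proprioceptor genes were detected for 5 of 6, with Spp1 at 47.3 ± 6.61, Etv1 at 25.1 ± 8.81 and Pvalb at 14.7 ± 4.54 TPM. Of the 4 TrkB mechanoreceptor genes 3 were detected, led by Shox2 at 112 ± 39.9 TPM, and Colq was not. Nociceptor genes were detected for 8 of 14: P2rx3, a purinergic receptor gene, stood at 177 ± 95.8 TPM, Calcb at 131 ± 35.7 TPM and Calca at 30.7 ± 5.17 TPM.

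Of 24 sensory neuron transcription factors 21 were detected. Sox11 was highest at 645 ± 732 TPM, and its value in D, 1482 TPM, set most of that spread. Isl1 and Pou4f1, which specify sensory neurons, stood at 591 ± 56.9 and 343 ± 308 TPM, and Pou4f3 at 102 ± 12.4 TPM. The Pou4f1 mean rests on D with 695 TPM, against 217 in B and 118 in C. Of the sodium channel genes 9 of 14 were detected, with Scn9a, which encodes Nav1.7, at 80.1 ± 10.8 TPM. Sensory transduction channels were detected for 7 of 14, led by P2rx3, followed by Trpv2 at 46.1 ± 19.2 TPM and Asic1 at 19.0 ± 7.19 TPM. Synaptic vesicle genes were detected for 12 of 13, with Snap25 at 214 ± 71.4 TPM. Of 9 neuropeptide genes 8 were detected; Gal stood at 94.9 ± 52.5 and Sst at 46.8 ± 28.3 TPM. The axon guidance list had 15 of 19 genes detected, with Nrp1 at 253 ± 172 TPM.

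All 13 cell cycle genes were detected, led by Cdk1 at 103 ± 49.1 TPM. Immediate early genes were detected for 9 of 12, with Fos at 227 ± 227 TPM and Jun at 82.4 ± 33.3 TPM. Hypoxia and glycolysis genes were detected for 7 of 11, with Aldoa at 1518 ± 395 TPM, and interferon response genes for 3 of 8, with Bst2 at 14.5 ± 12.1 TPM. In all, 8 of the 37 lists had a median above the 95th percentile of random lists in every library. They were RET receptor complex, cytoskeleton and axon growth, synaptic vesicle and glutamate release, neuropeptides, cell cycle, neuron, glia and erythroid. Random lists came from all genes with a count in any library, matched on length only, so percentiles do not rank lists by level. In D the erythroid list lay at percentile 95.3 with a median of 5.18 TPM. The neural crest list lay at 57.3 with 8.06 TPM.

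Hox transcripts, which mark position along the body axis, were concentrated in the middle and posterior paralog groups. Groups 7 to 10 held 83.3 ± 5.67% (SD, n = 3) of the summed Hox TPM. Hoxa7 stood at 92.1 ± 30.2, Hoxb9 at 88.7 ± 32.3, Hoxa10 at 76.1 ± 30.2, Hoxc10 at 60.4 ± 24.0 and Hoxd10 at 45.9 ± 17.1 TPM. Groups 11, 12 and 13 held 1.11 ± 0.30, 0.18 ± 0.015 and 0.17 ± 0.041%. Hoxa13 had no counts in any library. Of 39 Hox genes 22 were detected in every library, and 16 share exon bases with another gene, among them Hoxa7 and Hoxc10.

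**Figure D2:**
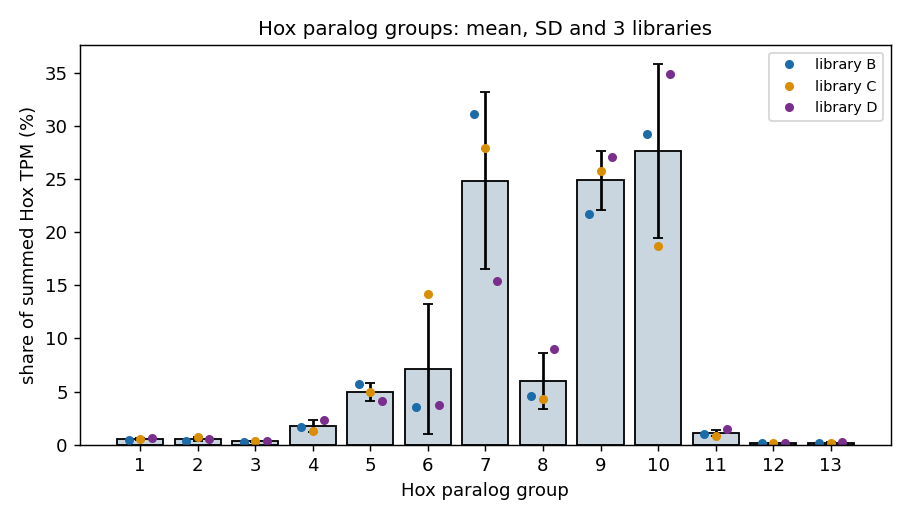
Share of summed Hox TPM per paralog group, in percent; bars are means, error bars SD over 3 libraries, and points the libraries. Groups 7, 9 and 10 hold 24.8, 24.9 and 27.6% in the mean.

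The next comparison asks which other cells the sorted pools held. Neuron markers exceeded glia and Schwann cell precursor markers in 3 of 3 libraries, by a log2 difference of list medians of 4.61 ± 1.69 (SD, n = 3; exact sign-flip p = 0.25). That difference was 5.59 in B, 5.57 in C and 2.65 in D. Of 11 glia markers 10 were detected. Fabp7, a fatty acid binding protein gene of glia, stood at 1864 ± 712 TPM, Ednrb at 922 ± 1055 and Sox10 at 70.0 ± 17.9 TPM. Erythroid genes were detected for 7 of 10, led by the embryonic globin Hbb-y at 1185 ± 903 TPM. Globins took 0.10% of counts in B, 0.056% in C and 0.010% in D.

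Other marker lists were lower in the mean over libraries. In D, though, the neural crest list had a median of 8.06 TPM, above the erythroid list at 5.18 TPM. None of 11 spinal cord progenitor and interneuron genes was detected in any library; Pax6 was highest at 0.07 ± 0.08 TPM, and Olig2 and Lbx1 stayed under 1 TPM. Of 6 motor neuron genes 1 was detected, Slc18a3 at 3.52 ± 1.63 TPM, and of 6 cartilage genes 1, Col2a1 at 11.8 ± 6.85 TPM. Sympathetic and chromaffin genes were detected for 6 of 11, with Chga at 114 ± 60.5 and Dbh, the noradrenaline synthesis gene, at 37.2 ± 40.6 TPM. Mesenchyme genes were detected for 5 of 10, macrophage genes for 4 of 10, endothelium genes for 2 of 8, neural crest genes for 2 of 6, skeletal muscle genes for 1 of 7, epithelium genes for 1 of 6 and pericyte genes for 0 of 4. C1qb led the macrophage list at 23.0 ± 5.68 TPM and Col1a2 the mesenchyme list at 24.2 ± 25.0 TPM. All 4 Y-linked genes had counts in each library and Xist stood at 2.73 TPM in B, 4.51 in C and 0.08 in D.

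Library D, from 3 embryos, was then set against B and C. Erythroid genes were lower in D for 10 of 10 members, with a log2 ratio of -3.12 ± 0.56 (approximate SE) for Hbb-y and -2.97 ± 0.85 for Hba-x. The list fell by limma's camera (adjusted p = 8.1e-08; adjusted p = 0.68 with an estimated correlation). Sympathetic and chromaffin genes were lower for 11 of 11, with -2.21 ± 0.54 for Chga and -2.90 ± 1.01 for Dbh. That list fell too (camera adjusted p = 0.00082, and adjusted p = 0.68 with an estimated correlation). Glia markers were higher for 8 of 10 and the list rose (camera adjusted p = 0.022, and adjusted p = 0.68 with an estimated correlation). Ednrb, the endothelin receptor gene, had a log2 ratio of 2.07 ± 0.37, against -0.51 ± 0.53 for Fabp7 and -0.15 ± 0.47 for Sox10. Neuron markers were lower for 12 of 14, with -1.26 ± 0.31 for Stmn2 and -1.37 ± 0.34 for Gap43. The neuron list fell (camera adjusted p = 0.048, and adjusted p = 0.68 with an estimated correlation), and with DESeq2's size factors it did not pass (adjusted p = 0.0507).

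Of 28 lists tested, 8 passed. The others were Y-linked genes, which rose (camera adjusted p = 0.012, 4 of 4 higher), axon guidance genes, which rose (0.047, 16 of 18 higher), cytoskeleton and axon growth genes, which fell (0.013, 17 of 21 lower), and neuropeptides, which fell (0.013, 8 of 9 lower). The cytoskeleton and neuron lists share members, so their calls are not separate. With an estimated correlation no list passed. That test rests on 1 residual degree of freedom and could hardly pass any list, so it decides nothing here. With DESeq2's size factors the axon guidance list did not pass either (adjusted p = 0.0507). Adjusted over all genes, edgeR's test passed no member of these lists. Adjusted over the list alone, it passed members of each list but axon guidance. These lists were picked because they passed camera on the same libraries, so such members are no separate support. RET signalling adaptors and targets were higher for 13 of 20 (camera adjusted p = 0.073), with 3.87 ± 0.40 for Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, 3.17 ± 0.62 for Dusp6 and -0.87 ± 0.44 for Dok5. That list passed with the trend in gene length and GC removed (adjusted p = 0.042, 14 of 20 higher), and not with an estimated correlation besides (adjusted p = 0.84).

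No single gene of 15727 passed edgeR's test in D at adjusted p 0.05, while 3046 had an unadjusted p under 0.05 and DESeq2 called 712. The higher genes with the smallest p had log2 ratios of 4.49 ± 0.45 for Ets1, 3.87 ± 0.40 for Spry2, 3.33 ± 0.35 for Grb10, 3.73 ± 0.40 for Tug1 and 4.09 ± 0.44 for Slitrk2. Among the lower genes, Xist had 441, 485 and 11 counts in B, C and D, Rn7sk 439, 296 and 30, Tspan32 296, 55 and 0, Cox6a1 21526, 12896 and 5293, and Hbb-bt 355, 408 and 34. Across 13080 protein-coding genes, which are not independent replicates, the log2 ratio of D had a Spearman correlation of 0.48 with gene length and -0.37 with GC content. With that trend removed, a step added after seeing the data, 8 lists passed, 5 of them among the 8 above: erythroid, sympathetic and chromaffin, glia, neuron and Y-linked. The other 3 were RET signalling adaptors and targets, skeletal muscle and immediate early genes (camera adjusted p = 0.042 for each). Axon guidance (0.92), cytoskeleton and axon growth (0.072) and neuropeptide genes (0.063) no longer passed. With the trend removed and an estimated correlation no list passed (adjusted p = 0.84 to 0.87 for these 8).

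**Figure D3:**
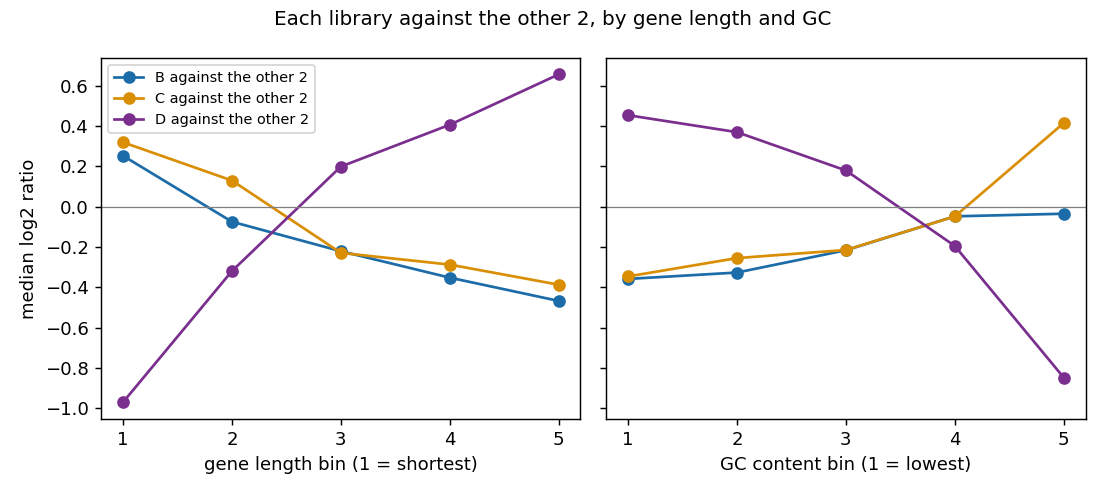
Median log2 ratio of each library against the other 2, over protein-coding genes in 5 equal bins of gene length (left) and GC content (right). Library D runs from -0.97 in the bin of shortest genes to 0.66 in that of longest, and C from -0.35 in the bin of lowest GC to 0.42 in that of highest.

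The same fit with B alone called 0 genes (174 at an unadjusted p under 0.05; DESeq2 called 1), and with C alone it called 119 higher and 4 lower. The genes highest in C included Cox5a, a cytochrome c oxidase subunit gene, with 239, 8831 and 201 counts in B, C and D, Ndfip1 with 435, 9609 and 972, and Pgls with 219, 3255 and 129. These genes were chosen after their values were seen. Call counts do not rank the libraries by how far they stood apart, because each fit estimates its own spread. The median absolute log2 ratio of CPM was 0.43 between B and C, 0.67 between B and D and 0.82 between C and D. With the length and GC trend removed, both higher and lower calls in C became more frequent. The 119 had a median GC of 56.4% and a median length of 1800 bases, against 49.6% and 3509 bases for the genes tested.

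Lists also stood apart in B and C. In B 7 of 28 passed camera. Erythroid (adjusted p = 3.4e-11, 8 of 10 higher), sympathetic and chromaffin (1.8e-10, 11 of 11), endothelium (1.5e-05, 7 of 8), neuropeptide (0.0024, 8 of 9) and skeletal muscle genes (0.048, 4 of 6) rose, while RET signalling adaptors and targets (0.048, 17 of 20 lower) and Y-linked genes (0.048, 4 of 4 lower) fell. None passed with an estimated correlation (adjusted p = 0.89 for each of the 7), and with the length and GC trend removed the erythroid, sympathetic and endothelium lists did. In C 2 lists passed camera: skeletal muscle genes fell (adjusted p = 1.4e-05, 6 of 6 lower) and erythroid genes rose (0.00041, 8 of 10 higher, with a median log2 ratio of 0.09). Neither passed with an estimated correlation (adjusted p = 0.98 for both), and with the trend removed the erythroid list did not (0.081). The skeletal muscle genes Actc1, Myf5, Myl1 and Myog passed edgeR's test adjusted over the list alone. They had 3, 0, 0 and 0 counts in C, against 114, 3, 30 and 22 in B and 90, 68, 18 and 29 in D. Myf5, with 3 counts in B, does not set C apart from B. The list was picked because it passed camera on the same libraries, so these members are no separate support. Each library entered all 3 fits, so the calls in B, C and D are not independent.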

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

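Alternatives that used protein-coding TPM, a length and GC correction or library C alone were chosen after seeing the data. Of 117 alternatives, 89 were counted as kept within a tolerance. A ratio could move by up to its SD between libraries, and a count or the coefficient of variation by a fixed fold. A kept count can hold other members, as for the lists called in D with the length and GC trend removed. Genes detected fell to 7151 at a limit of 5 TPM. With CPM in place of TPM, Ret over Ntrk2 moved from 1.09 to 0.18, because CPM leaves out gene length. Genes called in D, 0 with TMM, came to 8 with DESeq2's size factors, 1534 with no filter and 712 with DESeq2; the cause was not tested. Lists called in D went from 8 to 0 with an estimated correlation, which rests on 1 residual degree of freedom, and to 0 with the length and GC trend also removed. DESeq2's size factors gave 6, without the neuron and axon guidance lists. Genes called in C rose from 123 to 326 with the length and GC trend removed. Leaving out each library gave 12133 to 12714 genes detected, 0.95 to 1.29 for Ret over Ntrk2, 1.74 to 2.70 for Ret over Ntrk3, 4.11 to 5.58 for neuron over glia markers, 8 to 9 lists above the 95th percentile, and a biological coefficient of variation of 0.38 to 0.58. Neuron markers over the other 12 marker lists stayed above 0 in all 72 alternatives, from 3.68 to 13.3, and 20 of these moved by more than the spread between libraries. Depth limits genes near 3 counts, and the shallowest library, C, sets that limit.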

Other observations

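The lists of this paragraph were chosen after values were seen. Of 14 Notch pathway genes 11 were detected. Hes6 had the highest mean, 96.3 ± 127 TPM (SD, n = 3), with 24.1 in B, 243 in C and 21.7 in D. Heyl stood at 49.8 ± 56.9, Jag1, which encodes a Notch ligand, at 36.6 ± 50.2 and Hes1 at 36.3 ± 25.3 TPM, each highest in D, while Hes5, at 10.7 ± 9.50 TPM, was lowest there. Nrg1, the gene of a growth factor for Schwann cell precursors, stood at 168 ± 99.3 TPM, and its receptor gene Erbb3 at 62.0 ± 87.2 TPM, with 163 TPM in D. Of 8 neuregulin and ErbB genes 4 were detected, of 6 cytokine receptor genes of the gp130 family 4, and of 20 semaphorin genes 14. GABA-A receptor subunits were detected for 5 of 12. Ionotropic glutamate receptor subunits were detected for 5 of 16, led by Grik1 at 27.4 ± 19.4 TPM.

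The tests of sex composition on Xist and the Y-linked genes, the length trend in D, and the use of Fabp7 in the glia test were chosen only after the results were seen; the label put all samples in 1 group, so no biological difference between groups was tested.

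Long genes stood higher in D, with a Spearman correlation of 0.48 between gene length and log2 ratio; this is the pattern itself, so a technical and a biological origin cannot be told apart by it. Glia markers were also higher there, by a median log2 ratio of 1.10. Removing the length and GC trend left a median of 1.47 with an SD of 0.91 over 10 members, which argues against that trend as the cause. After removal 9 of 10 were higher, as a larger share of glia would give. Yet Fabp7, the glia marker of highest mean TPM, stood at -0.51 ± 0.53 (approximate SE) before removal. After removal it stood at -0.19, for which no SE was computed, while Ednrb, the highest by CPM, stood at 1.49. A larger share of glia and a different state of the glia cannot be told apart here, because the markers do not move alike; both remain hypotheses.

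Genes called higher in C were GC-rich: 82.9% of the 117 with a known GC lay above the median of the genes tested. That share restates the pattern, so whether a GC trend had a part in it cannot be told apart from other causes. Removing a smooth trend in length and GC left 107 of the 119 called, so such a trend is not the whole cause. Library C also held the largest share of counts in the rRNA-like features, 4.89%. What else sets these genes apart was not tested.

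Xist stood in D at 0.019 of its level in B (exact 95% counting interval 0.0092 to 0.033), where 1 female among 3 embryos would give 0.81 of it. A candidate explanation, found from these values, is a pool of male embryos only, although the label gives both sexes; the length and GC trend does not account for it, since the log2 ratio with the trend removed was -6.86. An all-male pool would raise Y-linked genes to 1.7 times the level in B, and their median was 5.05 with an SD of 2.63 over 4 genes, from 1.63 for Eif2s3y to 8.02 for Uty, so sex alone is not the whole cause. With the trend removed the median was 3.03 with an SD of 1.46, and whether the trend accounts for the remainder cannot be told apart from other causes, because the 4 genes scatter too widely.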
